A study of Mus musculus with 6 samples.

How the data were processed

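The samples were 6 RNA-seq libraries of brain endothelial cells from mice at postnatal day 7, 3 of a control group and 3 of a mutant group. The labels give the age as postnatal day 7 in the age, strain and description fields and in the harvest protocol, while a separate time field reads day 0 for all 6 libraries; day 7 was used. Per the labels' protocols, both groups carried Cdh5(PAC)-CreERT2, a tamoxifen-inducible Cre recombinase driven by the promoter of the endothelial cadherin gene Cdh5. Control mice had 1 floxed allele of Rbpj and mutant mice had both alleles floxed. Each pup received 100 µg of tamoxifen on postnatal days 1 and 2. Brains were digested with collagenase, passed over a Percoll gradient and enriched for CD31-positive cells on magnetic beads, and poly(A) libraries were made with a stranded kit, per the labels. Male and female mice of a mixed FVB/N and C57BL/6 background were pooled.

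The labels describe RNA pooled from many mice and sequenced in triplicate, and they leave open whether the 3 libraries of a group came from separate pools or from 1 pool. All p-values therefore measure the spread between these libraries, which may be technical. Counts of 2 libraries of a group differed by more than sampling noise in every pair, with a median chi-square of 1.81 to 2.62 times its expectation, against 5.32 to 6.15 times between groups. No 2 libraries were therefore merged as copies of 1 library, and each was counted as 1 replicate. Repeat libraries of 1 pool can differ by more than sampling noise too, so this does not show separate pools.

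The deposited table holds estimated counts per gene, as whole numbers that are not normalized. Per the submitters' processing notes, the authors used cutadapt 1.10, FastQC 0.10.1, HISAT2, StringTie 1.3.4 and edgeR, and the notes name the build GRCm39. The notes give no role, parameter or annotation for these tools, and whether the counting used the strand is not given in the sources used here. All 55450 gene identifiers of the table match the 55450 genes on the reference chromosomes of GENCODE release M21, which is built on GRCm38. Symbols and coordinates given here come from that annotation and are GRCm38 coordinates. Low counts pile up at multiples of 4: between 1118 and 1190 genes per library had a count of 4, against 316 to 365 genes with a count of 3 and 171 to 189 with a count of 5. Totals were 1.51 to 1.53 times the number of valid reads. About 4 units of count thus stand for 1 read pair, and precision follows the number of read pairs, not the size of the count. The deposited quality table gives, per the file headers, the count of raw and of valid reads per library, and the percent of valid reads, of bases above quality limits and of GC.

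Total counts per library ran from 75744913 to 82092461. The test had been planned for raw counts; the deposited estimates were already whole, so rounding changed nothing and the same test was used on them. Genes were kept with the edgeR function filterByExpr, which left 19549 genes. Library sizes were scaled by TMM, with factors of 0.978 to 1.009. The groups were compared with the quasi-likelihood F test of edgeR 4.0.16 with robust fitting, in R 4.3.3, with group as the only term. P-values were adjusted by Benjamini-Hochberg over all genes tested. A gene is called higher or lower below when its adjusted p was under 0.05. The SE of a log2 fold change was its size over the square root of F. Expression is given as CPM (counts scaled to library size), computed from the deposited counts with TMM scaling, as mean ± SD of 3 libraries.

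The test was checked on 5 simulated data sets with 200 changed genes each, drawn from the means, library sizes and dispersions of the real libraries and run on 19032 genes on average. It recovered 0.8% of genes changed 1.2-fold, 43.2% at 1.5-fold, 91.6% at 2-fold and 96.4% at 4-fold. Of 652 calls 72 were false, which is 11% and above the nominal level. Only 200 genes changed per simulated set, against 2812 called in the real data, so the adjusted p threshold was stricter in the simulation. The simulated library sizes were the deposited total counts, not numbers of read pairs, and the simulated counts lacked the steps of about 4. These shares describe the simulated setting and need not hold for the real comparison.

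A total of 32 gene lists was fixed before the data were examined. They cover the Notch pathway, arterial, venous and capillary markers, tip cell genes, blood-brain barrier genes, permeability genes, TGF-beta and BMP genes, cell cycle genes and inhibitors, extracellular matrix, shear stress, inflammation, interferon, hypoxia and glycolysis, endothelial identity and lymphatic markers. Further lists hold markers of pericytes and smooth muscle, fibroblasts, microglia, granulocytes, lymphocytes, erythroid cells, platelets, astrocytes, neurons, oligodendrocytes and choroid plexus, and also stress genes, mitochondrially encoded genes, and Y-linked genes with Xist. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 32 lists. Member counts are given from the test over all genes and adjusted over the list alone. With an estimated correlation, which rests on few residual degrees of freedom, no list passed, and its adjusted p is given beside each called list.

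The genes to be named were also fixed by rule before the data were examined. They were Rbpj, Cdh5, Apln, Aplnr and Cdc42. To these were added the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, at least a 2-fold change, a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted or clone-based name. From each list came the 3 called members with the smallest adjusted p, or 2 in the lists of other cells, stress, mitochondrial and Y-linked genes, or the most expressed member where none was called. The rule named 89 genes. Some of these genes and 1 of the lists are not reported here. Another 63 genes named below were chosen after their values were seen.

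Of the named genes, 3 share exon sequence with another detected gene on the same strand (Rnasek, Pkm and Xist) and 14 overlap a detected antisense gene (among them Gja5, Adgra2, Ccnd1, Ccnd2, Cdkn1a, Nid2, Cxcl10, Aldoa, Cd34, Tagln, Rarres2 and mt-Nd5). Near-identical copies such as Hspa1a and Hspa1b, and the alpha and beta globin genes, may have shared reads. Their values are uncertain to that extent.

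Alternatives set before the data were examined were RLE size factors, library size without a composition factor, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, glmTreat against a minimum change of 1.5-fold, the replicate number as a block, and each library left out in turn. For the lists, an estimated correlation and fry were added. Alternatives chosen after seeing the data were counts divided by 4, genes steady within groups to a ratio under 1.5, an offset for GC content and transcript length, and lists without markers of other cells. Their effect is given after the results. No sample was left out of the main comparison.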

Results

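Gene expression was measured by poly(A) RNA-seq in freshly isolated CD31-positive brain endothelial cells of mice at postnatal day 7, after tamoxifen on days 1 and 2. The control group had 3 libraries from mice with 1 floxed Rbpj allele, and the mutant group had 3 libraries from mice with both alleles floxed. Rbpj is the DNA-binding protein through which Notch receptors act on transcription. The series title places the comparison in a study of brain arteriovenous malformation, apelin signalling and Cdc42 activity. Control libraries held 78577192, 81484024 and 82092461 counts and mutant libraries 81556241, 77427556 and 75744913, where about 4 counts stand for 1 read pair. On the first principal component, with 33.1% of the variance, control libraries lay between -41.2 and -37.1 and mutant libraries between 37.1 and 40.7. On the second, with 18.8%, mutant library 3 lay at -55.6, apart from mutant libraries 1 and 2 at 31.2 and 26.2.

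Rbpj itself (ENSMUSG00000039191), on chromosome 5 from 53466152 to 53657362 on the plus strand (GRCm38), was lower in each mutant library than in each control library. Its expression was 54.3, 54.3 and 53.8 CPM in the control libraries and 47.9, 46.8 and 45.2 CPM in the mutant libraries. The log2 fold change was -0.21 ± 0.042 (SE), with an adjusted p of 0.0129 by the edgeR quasi-likelihood test. The gene-level count includes exons outside the deleted part, so it is a weak check of the deletion. Leaving out control library 1, control library 2 or mutant library 2 raised the adjusted p to 0.0571, 0.0543 or 0.051.

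Mutant libraries had higher expression of tip cell genes, of glycolysis and hypoxia genes and of interferon-stimulated genes, and lower expression of arterial, capillary and blood-brain barrier genes. Camera called these 6 lists with a preset correlation (adjusted p from 1.21e-18 to 0.00274), and none of them with an estimated correlation, which gave an adjusted p of 0.116 for the tip cell and hypoxia lists, 0.0697 for the interferon and arterial lists and 0.531 for the capillary and barrier lists. Libraries of enriched cells do not separate a change of expression within endothelial cells from a change in the mix of cells. Apln, which encodes the peptide ligand apelin, rose 3.03-fold from 592 ± 20.3 to 1795 ± 80.2 CPM (SD, n = 3). In all, 1477 genes were higher and 1335 lower in the mutant, 14.4% of the 19549 tested. Of these, 253 were at least 2-fold higher and 120 at least 2-fold lower. Most changes were small: 67.7% of the called genes changed by less than 1.5-fold, and the median absolute log2 fold change was 0.41. All 2812 called genes had no overlap between the groups, as did 34.1% of all tested genes, where chance gives 10% for 3 libraries against 3. Tested against a minimum change of 1.5-fold, 202 genes were higher and 89 lower. The count of lower genes was 807 without control library 1, 861 without control library 2 and 865 without mutant library 2. Among the 11738 genes with at least 5 CPM, 588 (5.0%) differed 2-fold or more between libraries of 1 group, and 1 of these, Gja5, was called.

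**Figure D1:**
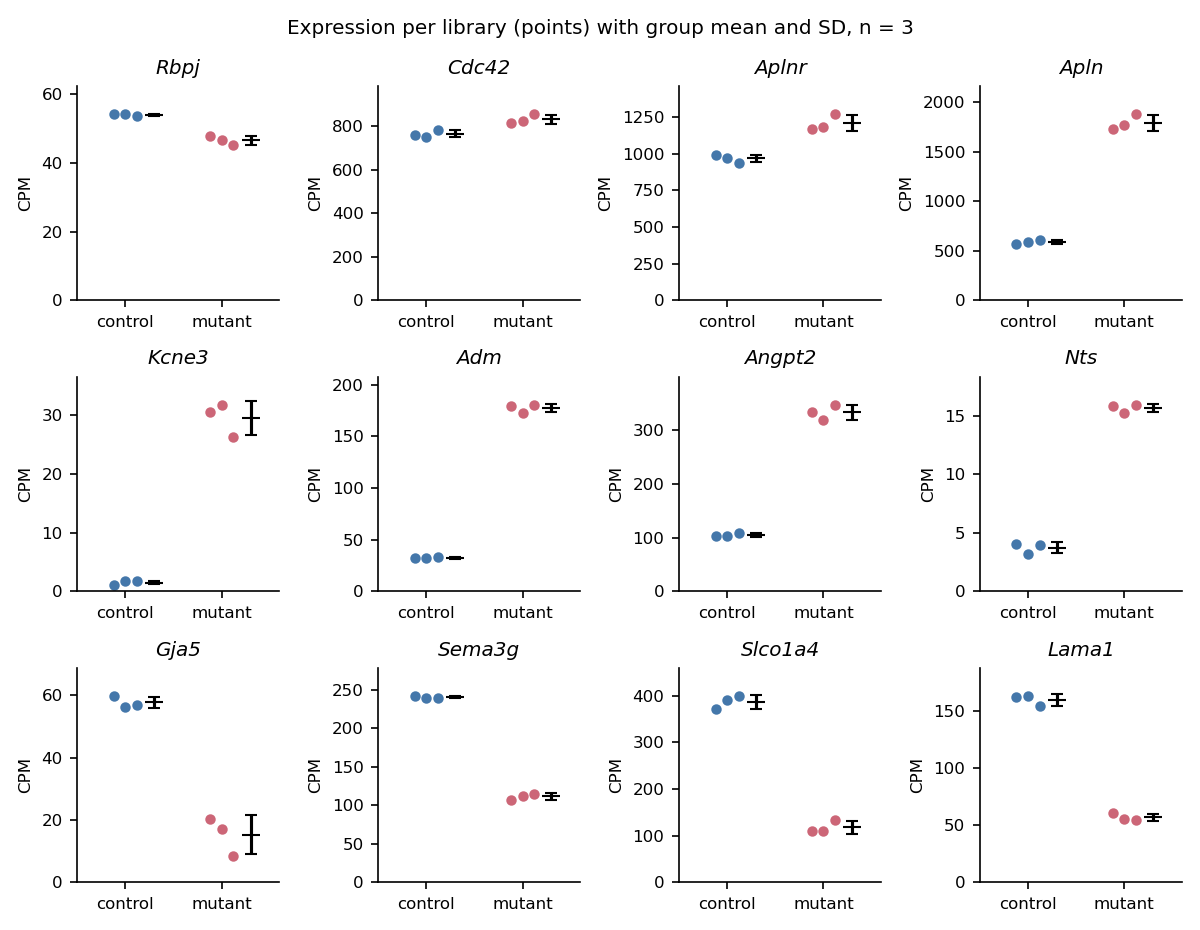
CPM of 12 genes in each library (points; control blue, mutant red), with the group mean and SD (black, n = 3) on linear axes that start at 0. Apln had a mean of 592 CPM in control and 1795 CPM in mutant libraries, and the 3 mutant values of Gja5 ran from 8.52 to 20.5 CPM.

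Kcne3, a potassium channel subunit, had the largest rise among genes changed at least 2-fold with a mean of at least 5 CPM, from 1.51 ± 0.32 to 29.5 ± 2.89 CPM (log2 fold change 4.29 ± 0.177 SE, adjusted p = 1.53e-05). Pcsk6, a proprotein convertase, rose from 7.16 to 55.2 CPM, a log2 fold change of 2.94 ± 0.062 (adjusted p = 1.65e-06). Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, changed by 2.75 ± 0.128, and Adm, which encodes the vasodilator peptide adrenomedullin, by 2.44 ± 0.040, on the log2 scale. The other rises of this size were Clca2 at 2.54, Dlk1, a non-canonical Notch ligand, at 2.51, the cadherin Cdh13 at 2.44, and the lactate transporter Slc16a3 at 2.26. The largest falls were in Syt15 at -1.97 ± 0.055, the arterial gap junction gene Gja5 at -1.91 ± 0.346, the protease-activated receptor F2rl1 at -1.76 and the organic anion transporter Slco1a4 at -1.72. Smooth muscle actin Actg2 (-1.55), the natriuretic peptide receptor Npr3 (-1.54), laminin Lama1 (-1.49) and Rnasek (-1.45), whose exons overlap another gene on its strand, followed. A total of 154 genes met the criteria for this ranking, 105 higher and 49 lower. The adjusted p of Gja5 was 0.0274, and it rose to 0.0902, 0.0854 and 0.083 without control library 1, 2 or 3, to 0.0993 without mutant library 2 and to 0.0566 without the low-count filter. The gene overlaps an antisense gene.

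Apelin and its receptor were both higher in the mutant libraries at the transcript level. Besides the rise of Apln given above (SE of the log2 fold change 0.044, adjusted p = 2.14e-06), the apelin receptor gene Aplnr rose by 0.32 ± 0.041, from 966 ± 27.1 to 1207 ± 54.5 CPM (adjusted p = 0.00198). Cdc42 had 766 ± 17.3 CPM in control and 833 ± 21 CPM in mutant libraries, a log2 fold change of 0.12 ± 0.033 that missed the threshold (adjusted p = 0.0512). Cdc42 passed the threshold under 8 of 17 alternatives. Its adjusted p was 0.0453 with RLE size factors, 0.027 with library size only, 0.0346 without the filter and 0.0412 with the stricter filter. It was 0.042 with DESeq2, 0.0438 with limma-voom, 0.0286 with counts divided by 4 and 0.0348 among steady genes. Under the other 9 Cdc42 was still not called. These were each library left out in turn, the replicate block, the GC and length offset and glmTreat.

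Notch pathway genes moved in both directions. Of 30 tested, 5 were higher and 4 lower, or 6 and 8 adjusted over the list alone. Lfng, which glycosylates Notch receptors, rose by 0.46 ± 0.037 (adjusted p = 0.000194), the Notch feedback regulator Nrarp by 0.37 ± 0.045 (adjusted p = 0.00141) and the endothelial receptor gene Notch4 by 0.33 ± 0.043 (adjusted p = 0.0022). Dll4 (0.21) and Heyl (0.13) were the other higher members. The lower ones were Hey1 (-0.52), Hes1 (-0.33) and the receptor genes Notch1 (-0.25) and Notch3 (-0.19), the last also a mural cell gene. Hey1 and Hes1 are transcriptional targets of Notch, as are the higher members Nrarp and Heyl, so called targets moved in both directions. With 1 library left out, the adjusted p of Hey1 rose to between 0.0744 and 0.154 in 5 of 6 fits, all but that without mutant library 1, while its log2 fold change in these 5 lay between -0.57 and -0.41. The adjusted p of Heyl rose to between 0.0898 and 0.138 in 5, all but that without mutant library 3, with a log2 fold change between 0.12 and 0.15. For Notch3 the adjusted p was 0.0919, 0.0875, 0.067 and 0.0744 without control library 1 or 2 or mutant library 1 or 2. Hes1 had 0.0518 and 0.0577 without control library 1 or 2, and Notch1 0.0544 and 0.0547 without control library 1 or mutant library 2. With library size only, the adjusted p was 0.062 for Hey1 and 0.0747 for Heyl, and without the low-count filter 0.0879 and 0.0501. For Heyl it was 0.0511 with limma-voom and 0.0634 with the GC and length offset. Camera did not call the list (median -0.09, adjusted p = 0.385).

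Arterial markers fell as a group. Of 30 tested, 19 were lower and 3 higher, or 20 and 3 adjusted over the list alone, with a median of -0.49. Sema3g fell from 240 ± 1.52 to 112 ± 4.22 CPM (-1.11 ± 0.038, adjusted p = 5.15e-06), the elastin gene Eln from 1502 ± 18.6 to 812 ± 17.4 CPM (-0.89 ± 0.030, adjusted p = 5.15e-06) and the growth factor gene Vegfc from 49.8 to 21.6 CPM (-1.20 ± 0.052, adjusted p = 1.51e-05). The higher members were Nrp1, Dll4 and Kcnj8, which is also a pericyte gene. By camera the arterial list was lower (adjusted p = 1.01e-08), with an adjusted p = 0.0697 with an estimated correlation. Fibroblast, astrocyte and microglia markers were lower in the same libraries, with medians of -0.52, -0.32 and -0.27. The pericyte and smooth muscle list was split: 5 of 21 members were higher and 8 lower, with a median of -0.05 and a mean of -0.30. Of the 30 arterial genes, 5 also stand in lists of other cells.

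Venous markers did not move as a group: 7 of 25 were higher and 8 lower, with the same counts adjusted over the list alone, a median of -0.01 and a camera adjusted p of 0.58. Bgn fell by 0.67 ± 0.032 (adjusted p = 2.1e-05) and the adhesion gene Vcam1 by 0.88 ± 0.052 (adjusted p = 5.25e-05), while Tmsb10 rose by 0.51 ± 0.036 (adjusted p = 0.000105). Capillary markers were lower in 8 of 12 cases and higher in 2 (Rgcc and Car4), also adjusted over the list alone, with a median of -0.38. Without control library 1 or 2 the adjusted p of Car4 was 0.0879 and 0.0846, and with the GC and length offset 0.0513. The chemokine gene Cxcl12 fell by 0.83, the lipid transporter Mfsd2a by 0.65 and the monocarboxylate transporter Slc16a1, from 3668 to 2414 CPM, by 0.60. Camera called this list lower (adjusted p = 0.00274), with an adjusted p = 0.531 with an estimated correlation. Astrocyte and microglia markers were lower in the same libraries, with medians of -0.32 and -0.27.

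Tip cell and angiogenic sprouting genes, which mark the leading cells of growing vessels, rose as a group. Of 30 tested, 23 were higher and 2 lower (Igfbp3 and Unc5b), or 26 and 2 adjusted over the list alone, with a median of 0.72. Trp53i11 rose from 77.5 ± 2.28 to 266 ± 11.2 CPM (1.78 ± 0.044, adjusted p = 1.65e-06) and Angpt2, a ligand of the Tie2 receptor, from 105 ± 3.07 to 333 ± 13.8 CPM (1.67 ± 0.043, adjusted p = 1.65e-06). Adm, named above, also stands in this list. Camera called it higher (adjusted p = 1.21e-18), with an adjusted p = 0.116 with an estimated correlation. Microglia, fibroblast and erythroid markers were lower in the same libraries, with medians of -0.27, -0.52 and -0.38.

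Hypoxia and glycolysis genes were higher in 18 of 32 cases and lower in 3, or 20 and 5 adjusted over the list alone, with a median of 0.44. The pyruvate kinase gene Pkm rose from 1003 ± 24.9 to 1725 ± 30.1 CPM (0.78 ± 0.032, adjusted p = 1.1e-05), though it shares exon sequence with another gene on its strand, and the aldolase gene Aldoa, which overlaps an antisense gene, rose by 0.63 ± 0.029 (adjusted p = 1.99e-05). The lower members were the glucose transporter gene Slc2a1 (-0.48), Ndrg1 (-0.42) and Ddit4 (-0.29). By camera these genes were higher (adjusted p = 7.83e-08), with an adjusted p = 0.116 with an estimated correlation. Of the markers of other cells, those of erythroid cells had a median of -0.38 and those of neurons 0.27.

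Extracellular matrix genes changed in both directions, with 18 of 49 higher and 19 lower, or 19 and 25 adjusted over the list alone. Lamb1 rose by 1.01 ± 0.042 (adjusted p = 1.23e-05) and the nidogen gene Nid2, which overlaps an antisense gene, by 0.98 ± 0.042 (adjusted p = 1.45e-05), while Lama1 fell from 160 ± 4.98 to 56.9 ± 3.08 CPM. The list's median was -0.17 and its mean 0.01, and camera did not call it (lower, adjusted p = 0.836), whereas fry, which tests the list alone, gave the opposite sign (adjusted p = 0.0448). Lama1 and 5 others of these genes also stand in lists of other cells.

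Blood-brain barrier genes were lower. Of 43 tested, 21 were lower and 2 higher (Foxf2 and Foxq1), or 26 and 3 adjusted over the list alone, with a median of -0.31. Without control library 1 or 2, Foxf2 had an adjusted p of 0.0608 and 0.0582, and that of Foxq1 lay between 0.0523 and 0.111 with any of the 6 libraries left out and was 0.0969 with the GC and length offset. Slco1a4 fell from 387 ± 14.5 to 118 ± 13.9 CPM (adjusted p = 5.74e-05). Adgra2, a gene of Wnt7 signalling in brain endothelium that overlaps an antisense gene, fell from 379 to 185 CPM (-1.03 ± 0.054, adjusted p = 3.18e-05). The Wnt pathway gene Nkd1 fell by 0.74 ± 0.051 (adjusted p = 0.000102). Camera called barrier genes lower (adjusted p = 1.01e-08), with an adjusted p = 0.531 with an estimated correlation. Astrocyte and fibroblast markers were lower in the same libraries, with medians of -0.32 and -0.52. Permeability genes were not called as a group (median 0.05, adjusted p = 0.58): of 15, Angpt2 and Nrp1 were higher and Mal (-1.17 ± 0.048), Cavin2 (-0.49 ± 0.043) and Aqp1 (-0.43) lower, or 4 and 4 adjusted over the list alone. The adjusted p of Aqp1 was 0.132, 0.114, 0.112 and 0.102 without control library 1, 2 or 3 or mutant library 2, 0.0632 with library size only and 0.0532 without the low-count filter.

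TGF-beta, BMP and vascular malformation genes were lower in 15 of 39 cases and higher in 5, or 16 and 5 adjusted over the list alone, with a median of -0.18. Smad1, Tgfb1, Braf and Map2k1 were among the higher members. For Braf the adjusted p was 0.0512, 0.0546 and 0.0508 without control library 2, control library 3 or mutant library 1, and that of Map2k1 lay between 0.0854 and 0.111 in every fit with 1 library left out except that without mutant library 1 and was 0.118 with the GC and length offset. Ltbp4, which binds latent TGF-beta, fell from 785 to 359 CPM (-1.13 ± 0.048, adjusted p = 1.4e-05), and the BMP target Id1 by 0.54 ± 0.039 (adjusted p = 0.000127). For this list camera gave a lower call (adjusted p = 0.00441), with an adjusted p = 0.117 with an estimated correlation. Fibroblast and microglia markers were lower in the same libraries, with medians of -0.52 and -0.27. Shear stress genes were lower in 9 of 21 cases and higher in 4, or 11 and 6 adjusted over the list alone, and were not called as a group (median -0.11, adjusted p = 0.204). The flow-responsive transcription factor Klf2 fell by 0.61 ± 0.030 (adjusted p = 2.39e-05), and Plxnd1 rose by 0.65 ± 0.035 (adjusted p = 3.33e-05), with Angpt2, Pecam1 and Dusp5 as the other higher members.

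Cell cycle genes were slightly higher: 11 of 50 were higher and 1, Ccnd2, was lower, or 13 and 1 adjusted over the list alone, with a median of 0.10. The replication factor Mcm6 rose by 0.27 ± 0.031 (adjusted p = 0.00123) and Ccnd1 by 0.26 ± 0.036 (adjusted p = 0.00274), while Ccnd2 fell by 0.26 ± 0.038; both cyclin genes overlap antisense genes. The camera call was higher (adjusted p = 0.000225), with an adjusted p = 0.116 with an estimated correlation. Lymphocyte markers had a median of 0.59 and microglia markers one of -0.27. Among 15 cell cycle inhibitors, Cdkn1a (0.72 ± 0.039, overlapping an antisense gene) and Ccng1 (0.31) were higher and Cdkn2b (-1.42 ± 0.064), Gadd45b (-0.83 ± 0.072) and Cdkn1c (-0.50) were lower, the same counts adjusted over the list alone. The median of the inhibitors was 0.03 and their mean -0.19, and camera did not call them (lower, adjusted p = 0.812).

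Interferon-stimulated genes were higher in 12 of 25 cases and not called in the other 13, or 16 higher and 1 lower adjusted over the list alone, with a median of 0.38. Rsad2 rose from 5.81 ± 0.406 to 13.6 ± 1.94 CPM (1.23 ± 0.124, adjusted p = 0.000576), the RNA sensor gene Ddx58 by 0.34 ± 0.041 (adjusted p = 0.00143) and Ifit3b from 1.33 to 2.96 CPM (adjusted p = 0.00308). Interferon-stimulated genes were called higher by camera (adjusted p = 1.15e-06), with an adjusted p = 0.0697 with an estimated correlation. Of the markers of immune cells, those of lymphocytes had a median of 0.59 (camera adjusted p = 0.0373), those of granulocytes and monocytes one of 0.26 (0.0595) and those of microglia one of -0.27 (0.000891). Inflammation and adhesion genes were mixed (5 of 28 higher, 4 lower, or 8 and 7 adjusted over the list alone; median 0.04, adjusted p = 0.58). Vcam1 and Icam1 (-0.36 ± 0.032) fell together with Cxcl1 and Sele, and Cxcl10 (0.78 ± 0.120), Ch25h, Madcam1, Ccl5 and Ccl2 were higher. With 1 library left out, the calls of Cxcl1, Sele, Ccl5 and Ccl2 were lost in 5, 5, 4 and 5 of 6 fits, with adjusted p up to 0.103, 0.139, 0.0769 and 0.12, and that of Ccl2 also with library size only (0.058).

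Endothelial identity markers did not move as a group (9 of 30 higher, 8 lower, or 11 and 10 adjusted over the list alone; median 0.01, mean -0.04, camera adjusted p = 0.977). Cd34, which overlaps an antisense gene, rose from 1392 to 2089 CPM (0.59 ± 0.039), and Bsg fell from 5074 to 3530 CPM (-0.52 ± 0.037) and the phosphatase gene Ptprb by 0.62 ± 0.055. Cdh5, which encodes VE-cadherin and whose promoter drives the Cre, went from 1525 ± 32.4 to 1377 ± 55.0 CPM (-0.15 ± 0.037, adjusted p = 0.038). That call was lost without control library 1, 2 or 3 (adjusted p = 0.0982, 0.161 and 0.0973), without mutant library 1 or 2 (0.125 and 0.159) and with the GC and length offset (0.089). Among 10 lymphatic markers, the neurotensin gene Nts (2.08 ± 0.114) and Flt4 (0.26) were higher and Ccl21a (-0.45 ± 0.037) and Mmrn1 (-0.42 ± 0.039) lower, or 3 and 3 adjusted over the list alone (median -0.03, mean 0.16, adjusted p = 0.977).

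**Figure D2:**
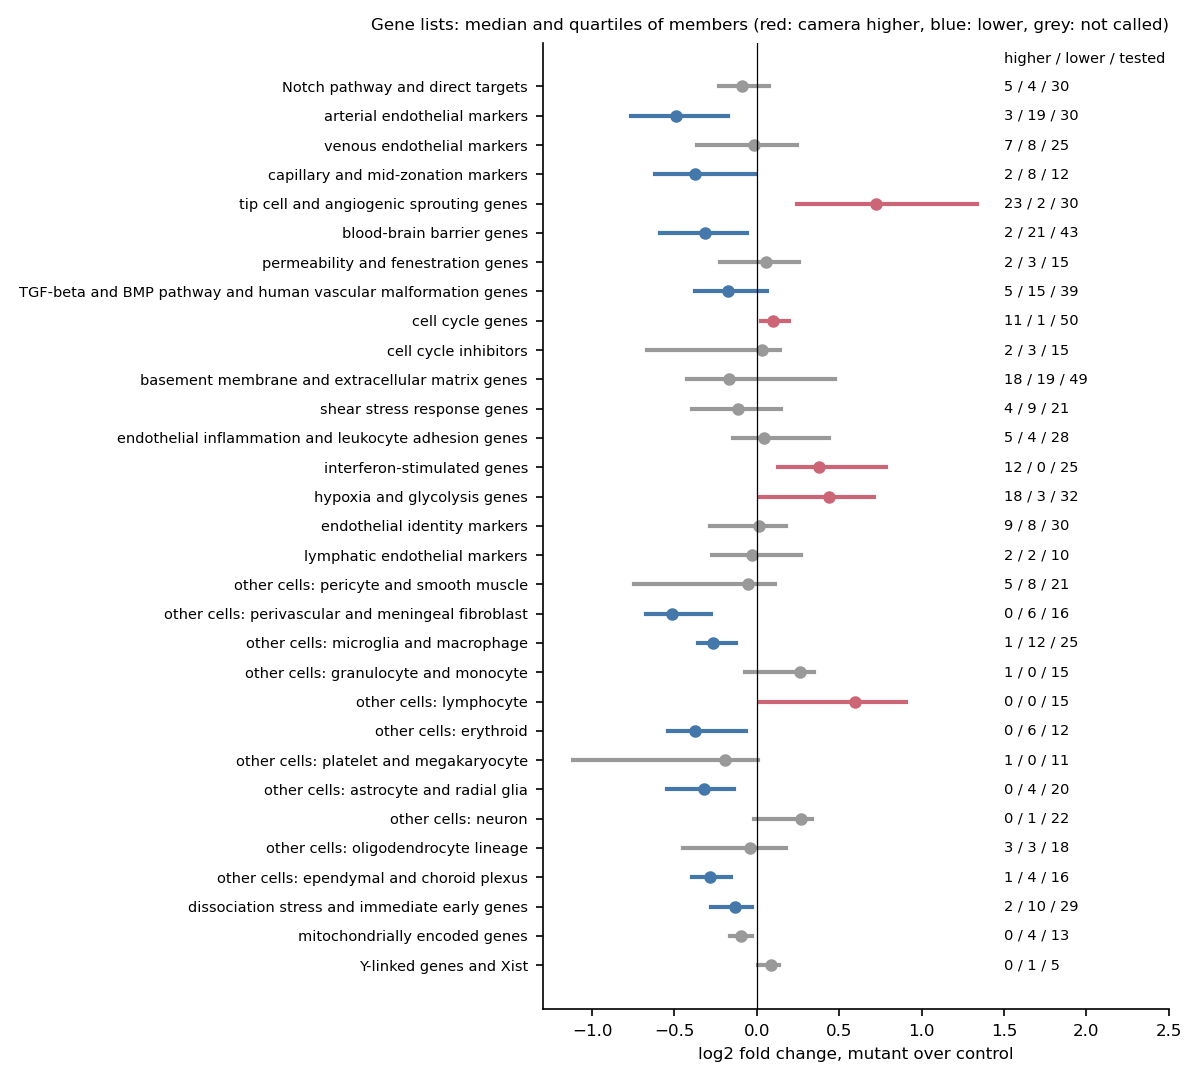
Median (point) and quartiles (line) of the log2 fold change, mutant over control, of the members of each gene list, with the number called higher, called lower and tested at the right. Red lists were called higher and blue lists lower by camera with a preset correlation, and the tip cell list had the highest median, 0.72.

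Markers of other cell types differed between the groups as well. Fibroblast markers were lower in 6 of 16 cases and not called in the other 10 (10 lower adjusted over the list alone), with a median of -0.52, where Ogn fell by 0.90 ± 0.069. Microglia and macrophage markers were lower in 12 of 25 cases (13 adjusted over the list alone) and higher in 1, with a median of -0.27. Fcrls fell by 0.45 ± 0.035, and the higher member, Spp1, which other cells also express, rose from 51.3 to 209 CPM (2.03 ± 0.085). Erythroid markers were lower in 6 of 12 cases and not called in the other 6 (7 lower adjusted over the list alone), with a median of -0.38. The globin gene Hba-a2 fell from 1683 to 1087 CPM and its near-identical copy Hba-a1 from 2079 to 1463 CPM. Astrocyte markers were lower in 4 of 20 cases (among them Clu, Aqp4 and Fgfr3; 6 lower and 1 higher adjusted over the list alone), with a median of -0.32, and Clu fell by 0.44 ± 0.070. Choroid plexus and ependymal markers were lower in 4 of 16 cases (Sostdc1, Folr1, Kcne2 and Aqp1) and higher in 1 (Rarres2), or 5 and 1 adjusted over the list alone, with a median of -0.28, and Sostdc1 fell by 0.83 ± 0.066. With 1 library left out, Rarres2 lost its call without control library 1 or 3 and mutant library 1 or 2 (adjusted p = 0.0509, 0.0591, 0.0653 and 0.066), and Aqp4, Fgfr3, Folr1 and Kcne2 lost theirs in 4, 5, 4 and 4 of 6 fits, with adjusted p up to 0.122, 0.128, 0.0732 and 0.0965. Camera called these lists lower, with adjusted p of 1.31e-06, 0.000891, 0.000204, 0.00468 and 0.00274 in that order. With an estimated correlation, the adjusted p = 0.531 for fibroblast, microglia, astrocyte and choroid plexus lists and 0.177 for the erythroid list. Among genes steady within groups the adjusted p of the astrocyte list was 0.0596.

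Pericyte and smooth muscle markers were split. Of 21, 5 were higher (Abcc9, Higd1b, Kcnj8, Ndufa4l2 and Cspg4) and 8 lower, or 6 and 9 adjusted over the list alone (median -0.05, mean -0.30, adjusted p = 0.168). Tagln, which overlaps an antisense gene, fell from 57.6 to 25.6 CPM, and Abcc9 rose from 336 to 481 CPM. In the granulocyte list Ngp was the 1 higher member of 15 (0.76 ± 0.169, adjusted p = 0.0276, lost without control library 1, 2 or 3 at 0.0699, 0.103 and 0.102 and without mutant library 1 or 2 at 0.094 and 0.0506), also adjusted over the list alone. The granulocyte list missed the threshold (median 0.26, adjusted p = 0.0595), which it passed at 0.0405 without control library 1, at 0.0321 without control library 2, at 0.013 without mutant library 3, at 0.0285 without the low-count filter and at 0.0463 with counts divided by 4. The lymphocyte list had 0 called members of 15 by edgeR, also adjusted over the list alone, against 6 higher and 0 lower at an unadjusted p under 0.05, 2 higher with DESeq2 and 1 with limma-voom. Its most expressed member, Ighm, had 45.0 ± 3.79 and 43.8 ± 2.75 CPM. Camera called that list higher (median 0.59, adjusted p = 0.0373), with an adjusted p = 0.531 with an estimated correlation, and the call was lost with the stricter filter (0.211), with counts divided by 4 (0.162), among steady genes (0.575), without control library 2 (0.0712) and without mutant library 1 (0.105) or 2 (0.0743). The platelet list had 1 higher member of 11, the integrin gene Itgb3 (from 10.0 to 24.6 CPM), also adjusted over the list alone (median -0.19, adjusted p = 0.777). In the neuron list Stmn2, also an arterial marker here, was the 1 lower member of 22, also adjusted over the list alone (-0.24 ± 0.045; median 0.27, adjusted p = 0.0626, and 0.013 without mutant library 3 and 0.0285 without the low-count filter). For Stmn2 the adjusted p was 0.0121, and 0.0554 and 0.0552 without control library 1 or 2. Among 18 oligodendrocyte markers, 3 were higher, among them Cspg4 and Mog, and 3 lower, Cldn11 (-0.51 ± 0.098), Olig2 and Bcan, or 3 and 4 adjusted over the list alone (median -0.04, adjusted p = 0.58). The adjusted p of Cldn11 was 0.0125, and 0.0536 without control library 1. With 1 library left out, Cspg4, Mog, Olig2 and Bcan lost their calls in 4, 5, 4 and 4 of 6 fits, with adjusted p up to 0.0796, 0.0987, 0.0678 and 0.074.

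Dissociation stress and immediate early genes were lower in 10 of 29 cases and higher in 2 (Klf6 and Fosl2), or 16 and 3 adjusted over the list alone, with a median of -0.13. The heat shock genes Hspa1a and Hspa1b, near-identical copies, fell from 136 to 63.5 CPM and from 174 to 78.1 CPM. Fosl2 had an adjusted p of 0.0571, 0.06 and 0.0501 without control library 2, control library 3 or mutant library 1. Camera called stress genes lower (adjusted p = 0.000742), with an adjusted p = 0.531 with an estimated correlation. Fibroblast and erythroid markers were lower in the same libraries, with medians of -0.52 and -0.38. Mitochondrially encoded genes were lower in 4 of 13 cases (mt-Cytb, mt-Nd5, mt-Nd4 and mt-Co1), also adjusted over the list alone, with a median of -0.10 and a camera adjusted p of 0.0953, which was 0.012 without control library 2 and 0.0438 without mutant library 2. The fall of mt-Cytb was 0.20 ± 0.043 on the log2 scale (adjusted p = 0.0195), and mitochondrial genes took 3.55% ± 0.327 of counts in control and 3.20% ± 0.140 in mutant libraries (SD, n = 3). Control library 3 had the highest share, 3.92%. There mt-Atp6 jumped to 3547 CPM, against 710 and 685 CPM in control libraries 1 and 2 and 681 to 835 CPM in mutant libraries. Part of the control mean and SD of this share thus comes from mt-Atp6. The adjusted p of mt-Cytb was 0.0815, 0.0692 and 0.0821 without control library 1, mutant library 1 or mutant library 2. With 1 library left out, mt-Nd5 and mt-Nd4 lost their calls in 5 of 6 fits, all but that without control library 2, and mt-Co1 in all 6, with adjusted p up to 0.124, 0.123 and 0.186; mt-Co1 also lost it with RLE size factors (0.0575), the stricter filter (0.0547), DESeq2 (0.0642) and counts divided by 4 (0.0701). Of 5 Y-linked genes and Xist tested, Xist alone was called, lower by -0.46 ± 0.085 (adjusted p = 0.00971), also adjusted over the list alone; it shares exon sequence with a gene on its strand (list median 0.08, adjusted p = 0.812).

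**Figure D3:**
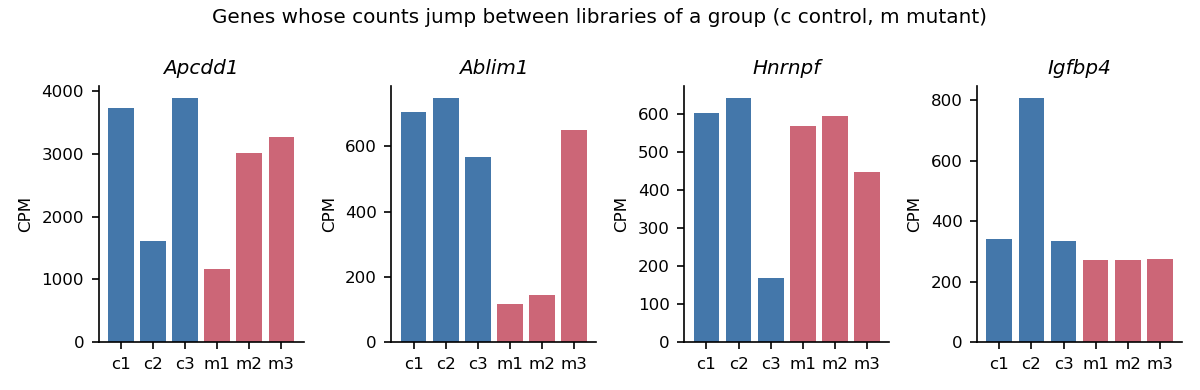
CPM in each library (bars; c control, blue; m mutant, red; numbers are replicates) of 4 abundant genes whose counts differ 2-fold or more between libraries of 1 group, on linear axes that start at 0. Apcdd1 ran from 1615 to 3881 CPM in control libraries and from 1159 to 3266 CPM in mutant libraries.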

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

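The alternatives with counts divided by 4, steady genes only, the GC and length offset and lists without other-cell markers were chosen after seeing the data; the others were planned. No called gene changed its direction under any alternative. Against a minimum change of 1.5-fold (glmTreat), 202 genes were higher and 89 lower, 160 of the former and 61 of the latter by at least 2-fold, and Rbpj (-0.215, adjusted p = 1) was no longer called; that test asks for a larger change by construction. Among the 12399 steady genes, 146 were at least 2-fold higher and 70 at least 2-fold lower, which is fewer genes tested. Leaving out each library in turn gave 807 to 1125 lower genes and an Rbpj log2 fold change of -0.234 to -0.188, with fewer samples. The adjusted p of Rbpj was 0.0571, 0.0543 and 0.051 without control library 1, control library 2 or mutant library 2. With an estimated inter-gene correlation, 0 lists were called higher and 0 lower, against 6 and 10; at an unadjusted p under 0.05 the same test gave 4 and 3 lists, and fry called 8 higher and 11 lower. The estimated correlation was -0.018 for the arterial, -0.007 for the interferon and -0.01 for the TGF-beta list, under the preset 0.01. These values argue against a higher correlation as the reason for the loss of those calls. For the capillary, barrier and fibroblast lists it was 0.691, 0.557 and 0.583. The part of the few residual degrees of freedom was not tested separately. Fry added venous (adjusted p = 0.00337), permeability (0.0124), cell cycle inhibitor (0.000576) and pericyte (0.0136) lists, did not call astrocyte (0.0582) and choroid plexus (0.0535) lists, and turned the matrix list from lower, not called, to higher (0.0448). The other counts of genes and lists stayed within 1.5 times of the main count, with 1100 to 1770 higher genes outside glmTreat. For the 88 other genes that the naming rule took, 1408 of 1494 values kept their call, 45 were lost under glmTreat and 33 elsewhere, and 8, all of Cdc42, passed the threshold; 0 reversed. For the 63 genes named after their values were seen, 866 of 1003 values outside glmTreat kept their call, 137 in 26 genes lost it and 0 reversed. All 23 higher tip cell genes were also called higher with the GC and length offset. The replicate number as a block gave 1106 higher and 953 lower genes and ended the calls of Gja5 (adjusted p = 0.0705), Cdh5 (0.078) and 14 of the genes named after their values were seen: Notch3 (0.0539), Fgfr3 (0.0543), Cxcl1 (0.0614), Cspg4 (0.0636), Braf (0.0637), Ccl5 (0.0675), Foxq1 (0.0842), Mog (0.0842), Sele (0.0934), mt-Nd4 (0.0954), Map2k1 (0.102), Ccl2 (0.104), mt-Co1 (0.115) and Heyl (0.119). Of the lists, it brought those of granulocytes (0.0131) and neurons (0.0424) past the threshold and ended no call. Same-numbered libraries did not deviate together (correlations -0.023, 0.01 and 0.023), and 3 of the 6 libraries correlated best with their own number, so the numbers were not taken as pairs. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05: 1 split, the real one, gave 1477 genes on one side and 1335 on the other, and the highest number on either side of the other splits was 3. Each other split mixes control and mutant libraries, so the difference between the groups enters its spread and keeps calls low. Their counts therefore give no rate of false calls. In data simulated with the deposited total counts, the spread and the 3 libraries per group of this series, 200 genes per set were changed. These totals stand above the depth in read pairs, and the simulated counts lacked the steps of about 4. Of the 1.5-fold changes 43.2% were recovered. The real comparison called 2812 genes and so had a less strict adjusted p threshold, and this share need not hold for it. The part of depth alone in the simulated recovery was not separated.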

Other observations

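The gene families of these first paragraphs were chosen after the values were seen, as were all tests below except the same-strand overlap and the low-oxygen genes. Solute carriers, the transporters of nutrients and ions, were called more often than the other tested genes: 29 of 301 were higher and 47 lower (adjusted p = 7e-06 by Fisher's exact test of called against not called, over 14 families). With RLE size factors 29 were higher and 45 lower, and with library size only 28 and 50. Among them, the vitamin transporters Slc52a3 (-0.82 ± 0.050 SE) and Slc5a6 (-0.77 ± 0.048) fell together with barrier transporters, while Slc16a6 rose from 38.8 to 103 CPM and the glutamate transporter Slc1a1 from 73.3 to 121 CPM. The split between higher and lower members missed the threshold (adjusted p = 0.075 by Fisher's exact test). In the test of called against not called, the 14 families held protein-coding genes only, while the other tested genes were of any type. Expression level was not matched either. Of genes with at least 5 CPM and less than a 2-fold difference within groups, 21.9% were called, against 14.4% of all tested genes. How much of the family results comes from gene type or expression level was not tested.

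Laminins and collagens also changed often, in both directions. Of 11 laminins, 3 were higher (Lamb1, Lama4 and Lamc1) and 6 lower, and of 42 collagens 7 were higher and 12 lower (adjusted p = 7e-06 for each family by the same Fisher's exact test). The basement membrane collagen Col4a3 rose from 17.6 to 49.4 CPM, and Col8a1 fell from 43.6 to 25.8 CPM. The fibroblast list, which holds Lama1 and some of these collagens, had a median of -0.52 in the same libraries, with 6 of 16 members lower. Potassium channel genes did not pass the test of called against not called (adjusted p = 0.87). Of 74, 10 were higher and 1, Kcne2, was lower under each of the 3 scalings; the adjusted p of that split was 0.075 by Fisher's exact test. Besides Kcne3, Kcnj15 rose from 8.45 to 25.9 CPM and Kcna5 from 25.4 to 53.9 CPM. Among cadherins, Pcdh17 rose from 18.6 to 66.7 CPM.

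Counts of 588 well-measured genes jumped 2-fold or more between libraries of 1 group. Poisson draws at the depth in read pairs gave 0.1 such genes on average, which argues against sampling noise. Same-strand exon overlap was found in 11.7% of them (95% Wilson interval 9.4 to 14.6%) and in 3.2% of the other genes. Reads shared through such overlap may thus contribute but cannot account for most. Reads shared with antisense genes or with near-identical copies were not tested. Pseudogenes made up 11.1% of the jumping genes and 3.8% of the others. The 6 values of 43.0% of the jumping genes fell on 2 levels, against 3.0% of jumping genes drawn from a normal spread, so all-or-none inclusion of part of a gene during assembly and counting is a candidate explanation, although a single odd library for any other reason would give 2 levels too. No biological explanation was tested.

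Markers of several other cell types were lower in the mutant libraries. A smaller share of all non-endothelial cells would lower every type alike, but the lists moved apart. The comparison took 114 genes of 9 lists, each with at least 5 CPM and in only 1 list of other cells. Medians ran from -0.516 for fibroblasts to 0.342 for granulocytes and monocytes. The permutation p of a rank test was 1e-05, the smallest that 100000 permutations can give, with genes taken as independent. Some of these genes, such as Lama1 and Kcnj8, also stand in lists of matrix or endothelial genes. How far that moved the lists apart was not tested. The share or the state of single cell types may differ between the groups, and so may the pools of mice. Neither was tested.

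Tip cell, hypoxia and glycolysis genes were higher in the mutant libraries. A purer endothelial preparation would raise endothelial identity markers by as much, but their median was 0.011, with an upper quartile of 0.175, against 0.724 for the tip cell list. Longer handling was taken to raise stress and immediate early genes, but their median was -0.132 with 10 members lower and 2 higher. Whether longer handling can also lower these transcripts was not tested, so a difference in handling between the groups stays open. Of 22 genes known to respond to low oxygen and outside every list, 9 were higher and 0 lower by edgeR. Their median of 0.238 lay above that of expression-matched random lists (two-sided permutation p = 0.0002, the smallest that 10000 lists can give, with genes taken as independent). This is in line with a wider low-oxygen response as a hypothesis, and loss of Rbpj acting on these genes by another route stays open.

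A strain difference carried with the floxed allele could change genes near Rbpj. Of 54 tested genes within 10 Mb, 5 (9.3%; C1qtnf7, Cd38, Fgfbp1, Ldb2 and Slit2) were called, against 14.4% of the others (two-sided Fisher's exact p = 0.34). So few of the 2812 calls lie there that such a change of nearby genes cannot account for most of them. It stays open for these 5 genes, and effects of strain sequence on genes elsewhere in the genome were not tested.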
